A study of Mus musculus with 95 samples.

How the data were processed

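Single mouse preimplantation embryos were profiled by Smart-seq2, a full-length method that reads polyadenylated RNA, per the labels' protocols. The embryos came from a hybrid cross of DBA fathers with F1 mothers (C57BL/6J × CBA/H) and were cultured in KSOM medium after zygotes were microinjected with wild-type or mutant Suv39h1 mRNA, per the labels. Which amino acid the mutant changes is not given in the sources used here. Per the submitters' processing notes, reads were checked with FastQC 0.11.7, trimmed with Trimmomatic 0.38 and quantified with kallisto 0.44.0, with mm10 and GRCm38.p6 as the genome builds. The deposited values are kallisto's estimated counts per transcript, per the file headers, and they are neither normalised nor whole numbers. The deposited files also hold kallisto's effective length in bases per transcript, per the file headers, which entered 1 alternative, and TPM values, which per the file headers kallisto wrote beside the counts, and which were not used. A read that fits several transcripts is shared out among them by kallisto, so genes of families with near-identical copies (Zscan4, Usp17l, Pramef, Obox) have uncertain counts. Coordinates and identifiers are those of GENCODE M21 on GRCm38.

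Estimated counts were summed over the transcripts of each of 54446 genes and rounded to whole numbers. Groups were taken from the labels, 12 in all, by injection and collection time. For 1 embryo the title and the characteristics name different injections, so it was placed in no group and entered no comparison. The libraries are single embryos, of which 0 fell under the limits set for shallow libraries (500000 counts, or 5000 genes with at least 5 counts). The labels give separate embryos and 4 experiments, but not litters, so embryos of 1 experiment are not known to be independent. At 90 h 1 wild-type and 1 mutant mRNA library have the title of another with the word replicate added, and the labels do not say whether these are other embryos or repeat libraries of 1 embryo. They were counted as separate, and correlated with their namesakes at 0.785 and 0.882, as against medians of 0.875 and 0.882 over all pairs of their groups. The p-values of fits that take the experiment into account measure the spread between embryos within experiments. The permutation tests exchanged embryos without regard to experiment, so their p-values ignore the pairing by experiment. Total counts bound the precision of low levels, and floors (3 counts over a group, used where all libraries of a group had 0) cover counting error only, since reads without molecular identifiers are not independent molecules.

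Comparisons used edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the filterByExpr filter, robust quasi-likelihood fits and two-sided tests, and the experiment letter as an additive block, as the labels state that it marks a shared experiment. Genes passed at a Benjamini-Hochberg adjusted p below 0.05 within a comparison, and every adjusted p given for a gene is of this test unless DESeq2 is named. The 3 injection groups of a collection time were fitted together, as were the 4 non-injected groups. Embryos of 1 labelled stage were fitted in their own models, with collection time added where it could be. Whether wild-type and mutant mRNA differed between times was an F test over all 12 groups.

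The design, the alternatives and 21 gene lists were fixed before the data were examined. The lists cover 2-cell genes, oocyte-expressed genes, ribosome biogenesis, ribosomal proteins, trophectoderm, pluripotency, primitive endoderm, polarity and junctions, H3K9 methylation factors, H3K9 demethylases, Polycomb, DNA methylation, p53 targets, stress, interferon response, DNA replication, mitosis, oxidative phosphorylation and mitochondrially encoded genes, and the markers of cumulus or granulosa cells and of sperm. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and by counting members past the test over all genes and adjusted over the list alone. Over all comparisons 346 such list tests were made, of which 80 passed with the preset correlation and, with all libraries, 0 with the estimated one, where the lowest adjusted p was 0.269.

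The genes named are Suv39h1, the genes of highest and lowest fold change among those past the threshold with a mean log2 CPM of at least 3 (6 and 6 for wild-type against mutant mRNA at one time, 3 and 3 elsewhere), and up to 3 members of each list with the smallest p. Symbols that are clone, accession or pseudogene names were left out, and some genes that this rule names are not reported here. The alternatives were DESeq2 1.42.0, median-ratio scaling, no filter on low counts, no replicate block, a transcript length offset, 1 fit of all 12 groups, leaving out each experiment or, in small comparisons, each embryo, and leaving out libraries titled as replicates. Fits without libraries that stand apart, with the Xist or Y-linked level as log2(CPM + 1) as a covariate, and with titled repeats summed were added after the data were seen. The models were tested on simulated counts drawn with the library sizes of the real embryos and 1 mean per gene over all embryos of a fit. In each design 100 genes were changed 4-fold and 100 changed 2-fold. The simulated counts held no other difference between groups, experiments or stages, so the shares recovered are for a simpler setting than the real one. No alternative scaling moved the median fold change by more than 0.1 on the log2 scale.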

Results

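The series holds 95 RNA-seq libraries of single mouse preimplantation embryos, 94 of which could be placed in a group. Zygotes of a hybrid cross were microinjected with mRNA of wild-type Suv39h1, a histone H3 lysine 9 methyltransferase, or with mutant Suv39h1 mRNA, or were not injected, and single embryos were collected at 48, 65, 75 or 90 h in 4 experiments, A to D. At 48 h there were 7 non-injected, 6 wild-type mRNA and 9 mutant mRNA embryos. The numbers in the same order were 8, 9 and 9 at 65 h, 8, 8 and 8 at 75 h, and 7, 8 and 7 at 90 h, where 1 wild-type and 1 mutant mRNA library may be repeats of another embryo's library, as their titles add the word replicate to that of another. Total estimated counts per embryo ranged from 803780 to 4366383, with a median of 1917409, and 8209 to 16937 genes had at least 5 counts. Levels are TMM-normalised CPM (read counts scaled by library size), given as mean ± SD over embryos, and fold changes are log2 estimates ± SE.

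The stage written on the labels differed between the injection groups from 65 h on. At 48 h every embryo was labelled 2-cell. At 65 h the wild-type mRNA group held 3 embryos labelled 2-cell, 1 labelled 3-cell and 5 labelled 4-cell, the mutant mRNA group held 2 labelled 3-cell and 7 labelled 4-cell, and the non-injected group held 3 labelled 4-cell and 5 labelled with more cells. At 90 h, 8 of 8 wild-type mRNA embryos were labelled 8-cell or earlier, against 1 of 7 mutant mRNA embryos and 0 of 7 non-injected embryos. A comparison at one collection time is therefore also a comparison of unlike mixtures of labelled stages at 65, 75 and 90 h.

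The first question was how much Suv39h1 RNA the embryos held. Suv39h1 (ENSMUSG00000039231.18) lies on the minus strand of chromosome X, 8061171 to 8074760 in GRCm38. The counts sum all annotated transcripts of the gene, and reads of injected and endogenous RNA are added together. At 48 h its level was 460 ± 255 CPM (n = 6) after wild-type mRNA, 239 ± 90.9 CPM (n = 9) after mutant mRNA and 101.6 ± 47.9 CPM (n = 7) without injection. Both injected groups exceeded the non-injected embryos, with log2 fold changes of 1.90 ± 0.37 (adjusted p = 0.0389) for wild-type and 1.35 ± 0.33 (adjusted p = 0.0482) for mutant mRNA in edgeR's quasi-likelihood test. The mutant call was lost without the experiment block (adjusted p = 0.168), with median-ratio scaling (0.0528), with a transcript length offset (0.0567), and without non-injected replicates 1 and 3 (0.98 ± 0.36, adjusted p = 0.0798). In 1 fit of all 12 groups both calls were lost (adjusted p = 0.0832 for wild-type and 0.354 for mutant mRNA). Without experiment A, C or D the wild-type call was lost (0.219, 0.251 and 0.170), and without A, B, C or D the mutant call was (0.161, 0.105, 0.240 and 0.138). Wild-type and mutant mRNA embryos did not differ at the threshold at 48 h (0.55 ± 0.35, adjusted p = 1). At 65 h the levels were 57.2 ± 40.1, 29.9 ± 19.3 and 35.9 ± 27 CPM for wild-type mRNA, mutant mRNA and no injection, and at 90 h they were 29.7 ± 16.2, 23.3 ± 7.01 and 34.7 ± 14.5 CPM. No comparison of Suv39h1 between injection groups at 65, 75 or 90 h passed, the lowest adjusted p being 0.254 for wild-type against mutant mRNA at 65 h (1.05 ± 0.46).

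**Figure D1:**
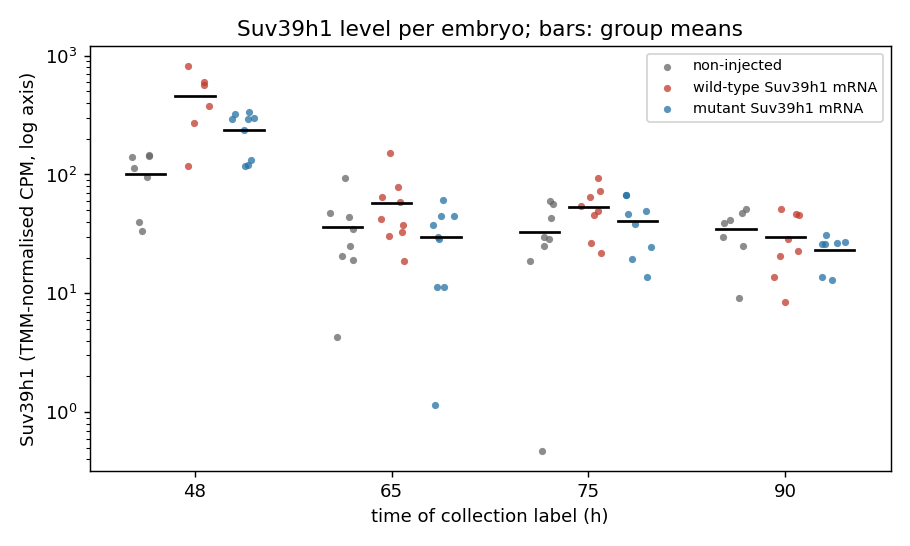
Suv39h1 level of each embryo in TMM-normalised CPM (vertical axis, log scale) by collection time in hours (horizontal axis), with 1 point per embryo, colours for the injection groups and black bars for group means. The 48 h means are 460 CPM after wild-type mRNA, 239 CPM after mutant mRNA and 101.6 CPM without injection, and the lowest point is non-injected 75 h replicate 1 at 0.468 CPM.

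The non-injected embryos show the course of development in culture. Between 48 and 65 h oocyte-expressed genes fell and ribosomal protein genes rose. Adjusted over the list alone, 31 of 36 measured oocyte-expressed genes fell and 1 rose (29 and 1 over all genes tested; list median -3.27), among them Zar1l, an oocyte gene (-3.53 ± 0.73, adjusted p = 0.00119). Of 79 ribosomal protein genes, 73 rose over the list alone and 61 over all genes (median 1.79), with Rpl15 at 2.03 ± 0.37 (adjusted p = 0.000421) and Rpl32 at 2.57 ± 0.54 (adjusted p = 0.00138). Genes of oxidative phosphorylation rose for 37 of 67 members over the list alone, and 2 fell (median 1.11). Pluripotency genes rose for 8 of 18 members, including Pou5f1 (2.12 ± 0.39), Tdgf1 (4.72 ± 0.83) and Klf2 (3.46 ± 0.70), and Gata6, a primitive endoderm transcription factor, rose by 4.37 ± 0.73. Of the genes transiently expressed around the 2-cell stage, 6 of 20 fell over the list alone. Zscan4a, a member of a family of near-identical copies whose reads cannot be assigned with certainty, fell by 7.85 ± 0.97 on the log2 scale, and Tet3, a DNA demethylation enzyme, fell by 3.48 ± 0.77. Ribosome biogenesis genes rose for 8 of 46 members (median 0.49, camera adjusted p = 0.0113, adjusted p = 0.865 with an estimated correlation). Suv39h1 itself was lower at 65 h (-1.52 ± 0.54, adjusted p = 0.0326). The oocyte list had a camera adjusted p of 6.65e-10, the ribosomal protein list 2.53e-18, the oxidative phosphorylation list 2.18e-08, the pluripotency list 0.00358 and the 2-cell list 0.000756, and with an estimated correlation each had an adjusted p = 0.685. Without non-injected 75 h replicate 1, a library that stands apart and shares this fit, 33 of 36 oocyte-expressed genes fell and 2 rose over all genes (median -3.38, adjusted p = 4.22e-05 with an estimated correlation), and 5010 genes passed.

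Several genes were nearly silent at one of these times. Smpdl3a had 0.0488 CPM at 48 h, from 1 count over the group, and 54 ± 17.1 CPM at 65 h (adjusted p = 3.25e-07). Aqp3, a water and glycerol channel, had 0.0621 CPM from 1 count and then 18.8 ± 12.6 CPM (adjusted p = 5.49e-05), and the growth factor gene Fgf3 had 0.305 CPM from 3 counts and then 41.7 ± 14.6 CPM (adjusted p = 9.24e-05). In the other direction Cmya5 went from 49.2 ± 34.6 CPM to 0.178 CPM, 2 counts over the group (adjusted p = 3.06e-05). In all, 3537 of 11640 genes passed in edgeR (1634 higher and 1903 lower at 65 h; n = 8 against 7). Without experiment C, which holds 4 of the 8 embryos at 65 h, 78 genes passed, and without experiment D 2189 passed.

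Between 65 and 75 h some genes of the trophectoderm, the outer lineage of the blastocyst, rose and some 2-cell genes fell. Cdx2, a trophectoderm transcription factor, had 0 counts in all 8 embryos at 65 h and 13.4 ± 13.7 CPM at 75 h, at least 66.8-fold higher against a floor of 3 counts over the group (adjusted p = 0.00559). Enpep and Tinagl1 were at least 74-fold and at least 68.2-fold higher by the same floor. Over the list alone 6 of 16 trophectoderm genes rose (3 over all genes; median 1.09, camera adjusted p = 0.000198, adjusted p = 0.773 with an estimated correlation). Pou5f1 rose by 1.78 ± 0.36 and Tfcp2l1, another pluripotency factor, by 3.37 ± 0.67. Over the list alone 11 of 20 2-cell genes fell (5 over all genes; median -2.38, camera adjusted p = 0.000439, adjusted p = 0.924 with an estimated correlation), with Zfp352 at -5.76 ± 1.21. Among polarity and junction genes 1 of 21 rose over the list alone, and none of 67 genes of oxidative phosphorylation passed (medians 0.62 and 0.35, camera adjusted p = 0.0185 and 0.0328, adjusted p = 0.924 with an estimated correlation for both). The oxidative phosphorylation call was lost with no replicate block (0.445). Without non-injected 75 h replicate 1, 6 of its genes rose over all genes (median 0.60, camera adjusted p = 5.09e-12, adjusted p = 0.294 with an estimated correlation). In all, 223 genes passed in edgeR (73 higher and 150 lower; n = 8 against 8). One library stood apart from its group, non-injected 75 h replicate 1, with a median ribosomal protein level of 0.554 log2(CPM + 1) against 5.34 or more in each of the other 93 assigned libraries. Without it 863 genes passed, and 15 of 36 oocyte-expressed genes fell and 1 rose over all genes (median -1.65, adjusted p = 0.00108 with an estimated correlation; with it 0 fell and 1 rose, median 0.32). Without experiment B 540 genes passed, without experiment D 8, and without experiment C 0.

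Between 75 and 90 h some trophectoderm, junction and p53 target genes rose. Over the list alone 9 of 16 trophectoderm genes rose and 1 fell (median 1.90), including the keratin gene Krt8 (4.60 ± 0.74, adjusted p = 0.000206), Id2 (5.41 ± 0.76) and Fabp3 (5.66 ± 0.93). Among polarity and junction genes 8 of 21 rose and 2 fell over the list alone, with Ezr, an apical membrane linker, at 4.07 ± 0.76. Among p53 target genes 6 of 21 rose over the list alone, with Ccng1 at 3.43 ± 0.56. The camera adjusted p was 9.30e-06 for trophectoderm and 0.00132 for both other lists, and with an estimated correlation each had an adjusted p = 0.269. Genes of oxidative phosphorylation rose for 10 of 67 members over all genes and 6 over the list alone (median 0.77, camera adjusted p = 8.55e-09, adjusted p = 0.410 with an estimated correlation). Mitosis genes fell for 4 of 30 members, ribosome biogenesis genes for 2 of 46 and 2-cell genes for 4 of 20. In that order the medians were -0.54, -0.47 and -0.81, and the camera adjusted p was 0.0163, 0.0175 and 0.0175. With an estimated correlation the adjusted p was 0.269, 0.726 and 0.430. Without non-injected 75 h replicate 1, 21 genes of oxidative phosphorylation rose, 10 mitosis genes fell and 1 rose, and 21 ribosome biogenesis genes fell, all over all genes. Their medians were then 0.54, -0.38 and -0.65 (adjusted p = 0.417, 0.229 and 0.229 with an estimated correlation). The 2-cell call was lost without that library (0.0607) and with no replicate block (0.0547). Nanog, a pluripotency factor, rose by 2.83 ± 0.58, and the highest fold changes among abundant genes were those of Lgals1 (7.08 ± 0.95) and Tpp1 (7.04 ± 0.87). Oocyte-expressed genes fell for 27 of 36 members and rose for 2 over the list alone, with 19 and 1 over all genes (median -3.99, adjusted p = 0.269 with an estimated correlation). Without non-injected 75 h replicate 1, whose oocyte list median was 7.004 against at most 2.34 log2(CPM + 1) in the other 7 embryos, 18 fell and 3 rose over all genes (median -2.09, adjusted p = 0.0415 with an estimated correlation). Npm2 (-4.37 ± 0.60) and Nlrp14 (-3.95 ± 0.70) also passed without that library (-4.03 ± 0.54 and -3.08 ± 0.49). Trim60, Obox2 and Fbxw22 had 0 counts in all 7 embryos at 90 h, at least 737-fold, 546-fold and 407-fold lower by the floor of 3 counts over the group. Their 75 h means of 159 ± 446, 118 ± 330 and 87.6 ± 242 CPM rest on replicate 1, at 1261, 933 and 687 CPM against at most 2.94, 3.15 and 4.50 CPM in the other 7. In all, 1814 genes passed in edgeR (873 higher and 941 lower; n = 7 against 8), 2958 without that library, 983 without experiment A, 2737 without B, 9 without C and 1201 without D.

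At 48 h, when all embryos were labelled 2-cell, wild-type and mutant mRNA embryos were compared first. No gene passed in edgeR (0 of 12338, with 210 at an unadjusted p below 0.05), while DESeq2 called 125 and edgeR with no filter on low counts 23. Zscan4c, from the same family of near-identical copies, stood at 2.17 ± 0.76 (adjusted p = 1). The 25 measured 2-cell genes had a median of 0.27 and none passed over the list alone (camera adjusted p = 1.97e-05, adjusted p = 0.881 with an estimated correlation). Ribosomal protein genes had a median of 0.17 (camera adjusted p = 0.000459, adjusted p = 0.881 with an estimated correlation; 0.0555 in the fit with no replicate block). In simulated data of this design 41% of genes changed 4-fold and 4% of genes changed 2-fold were recovered, over 12338 genes.

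Each injected group was then set against the non-injected embryos at 48 h. After wild-type mRNA 14 genes passed (11 higher and 3 lower; n = 6 against 7), with Slco4a1, an organic anion transporter, at 2.61 ± 0.52 (adjusted p = 0.0389) and Tmem92 at 1.43 ± 0.28 (adjusted p = 0.0389) among the higher ones. Hmgb3, a high mobility group protein gene, stood at -1.19 ± 0.23 (adjusted p = 0.0389) and Prps1, an enzyme of nucleotide synthesis, at -1.28 ± 0.26 (adjusted p = 0.04997) among the lower ones. After mutant mRNA 116 genes passed (72 higher and 44 lower; n = 9 against 7), among them Slco4a1 (2.39 ± 0.49), Dhrs3, a retinal reductase (2.51 ± 0.47), Zfp352, a 2-cell gene (1.38 ± 0.34), and Kdm6b, an H3K27 demethylase (1.28 ± 0.31), all higher. Rps4x (-1.32 ± 0.27), Rpl39 (-1.14 ± 0.25) and Dkc1, a ribosome biogenesis factor (-0.91 ± 0.20), were lower. Of the genes named in these comparisons Hmgb3, Prps1, Rps4x, Rpl39 and Dkc1, all lower, and Suv39h1, higher, lie on the X chromosome. Of 25 2-cell genes 12 rose after wild-type mRNA over the list alone and 0 over all genes (median 1.42), and 7 rose after mutant mRNA over the list alone and 1 over all genes (median 0.89). The camera adjusted p was 9.47e-11 and 1.47e-05, with adjusted p = 0.448 and 0.469 with an estimated correlation. Ribosomal protein genes fell for 41 of 79 members after mutant mRNA over the list alone and for 3 over all genes (median -0.74, camera adjusted p = 8.38e-22, adjusted p = 0.419 with an estimated correlation), and for 0 after wild-type mRNA (median -0.57, camera adjusted p = 9.47e-11, adjusted p = 0.448 with an estimated correlation). Oocyte-expressed genes rose for 10 of 38 members after mutant mRNA and for 1 after wild-type mRNA, both over the list alone (0 over all genes; medians 0.72 and 0.49, camera adjusted p = 1.36e-06 and 3.80e-05, adjusted p = 0.469 and 0.448 with an estimated correlation). Ribosome biogenesis genes fell for 1 of 46 members after mutant mRNA over all genes and for 2 after wild-type mRNA over the list alone. The medians were -0.44 and -0.53 (camera adjusted p = 1.36e-06 and 1.90e-07, adjusted p = 0.524 and 0.448 with an estimated correlation). In both comparisons 0 of 64 genes of oxidative phosphorylation and 0 of 30 mitosis genes passed. After mutant mRNA their medians were -0.55 and -0.19 (camera adjusted p = 2.46e-08 and 0.00925, adjusted p = 0.419 and 0.510 with an estimated correlation). After wild-type mRNA they were -0.45 and -0.31 (6.79e-06 and 0.00311, adjusted p = 0.448 with an estimated correlation for both). None of 17 pluripotency genes passed after mutant mRNA (median -0.70, camera adjusted p = 0.0181, adjusted p = 0.419 with an estimated correlation). None of 34 DNA replication genes passed after wild-type mRNA (median -0.41, camera adjusted p = 0.0157, adjusted p = 0.448 with an estimated correlation).

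These counts at 48 h moved with a few libraries and with the model. Non-injected replicates 1 and 3 were the only 2 non-injected 48 h embryos of experiment B. They had median correlations with their group of 0.817 and 0.739, against 0.882 or more in the other 5, and Suv39h1 levels of 39.9 and 33.5 CPM. Without them 447 genes passed for wild-type and 1116 for mutant mRNA. Without experiment B the counts were 705 and 627, and without experiment A or C 0 genes passed in both comparisons. Without experiment D 1 and 0 genes passed. Without non-injected replicates 1 and 3 Kdm6b no longer passed for mutant mRNA (0.94 ± 0.32, adjusted p = 0.0631). The mitosis list call after mutant mRNA was lost without those libraries (camera adjusted p = 0.122), while that after wild-type mRNA stayed (0.0316). Over all genes and without them, 11 of 25 2-cell genes rose in both comparisons, oocyte-expressed genes rose for 11 of 38 members after wild-type and 19 after mutant mRNA, and ribosomal protein genes fell for 3 and 17 of 79. With an estimated correlation the adjusted p was then 0.187 and 0.350 for 2-cell genes, 0.292 and 0.350 for oocyte-expressed genes, and 0.502 and 0.377 for ribosomal protein genes. In 1 fit of all 12 groups 1 gene passed in each comparison, and with no filter on low counts 295 and 434 did. With the summed level of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty as a covariate 113 and 363 passed. With no replicate block 0 genes passed for mutant mRNA, and DESeq2 called 546 for wild-type and 778 for mutant mRNA.

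Wild-type and mutant mRNA embryos differed at 65 h in 56 of 10393 genes in edgeR, 41 higher and 15 lower after wild-type mRNA (n = 9 against 9). The highest fold changes were those of Pramef17, from a family of near-identical copies (5.55 ± 1.2, adjusted p = 0.0411), Apol7b (3.92 ± 0.87, adjusted p = 0.0429), Ccser1 (3.83 ± 0.79, adjusted p = 0.0357), Robo1, an axon guidance receptor (3.72 ± 0.81, adjusted p = 0.0405), Zfp677 (3.58 ± 0.83, adjusted p = 0.0458) and Mgll, monoglyceride lipase (2.55 ± 0.55, adjusted p = 0.0405). Among the lowest were Vnn1, pantetheinase (-3.39 ± 0.80, adjusted p = 0.0475), Ube2u (-3.38 ± 0.78, adjusted p = 0.0437), Fdx1, an electron donor of mitochondrial P450 enzymes (-3.33 ± 0.74, adjusted p = 0.0415), and Casp6, a caspase (-2.23 ± 0.52, adjusted p = 0.0458). Rarb, a retinoic acid receptor, had 0.103 CPM after wild-type mRNA, from 2 counts over the group, against 8.85 ± 9.92 CPM (adjusted p = 0.00530).

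Among the lists at 65 h, 7 of 18 measured 2-cell genes rose in wild-type over mutant mRNA embryos when adjusted over the list alone and 0 over all genes (median 2.42, camera adjusted p = 4.13e-07, adjusted p = 0.350 with an estimated correlation). Usp17lb stood at 3.39 ± 0.89 (adjusted p = 0.0744) and Zscan4d at 3.35 ± 0.99 (adjusted p = 0.108), both from families whose copies share reads. Mdm2, a p53 target, rose by 1.06 ± 0.23 (adjusted p = 0.0415) as the only 1 of 16 p53 targets to pass (median 0.69, camera adjusted p = 0.0403, adjusted p = 0.548 with an estimated correlation). Of 25 factors of H3K9 methylation other than Suv39h1, Setdb1, another H3K9 methyltransferase (1.07 ± 0.34, adjusted p = 0.129), and its partner Atf7ip (1.25 ± 0.34, adjusted p = 0.0812) rose over the list alone and 0 passed over all genes (camera adjusted p = 0.0746). None of 79 ribosomal protein genes passed, but the list median was -0.59 (camera adjusted p = 9.54e-20, adjusted p = 0.409 with an estimated correlation), with Rpl13a at -0.84 ± 0.25 (adjusted p = 0.107). None of 17 pluripotency genes passed (median -0.60, camera adjusted p = 0.000821, adjusted p = 0.350 with an estimated correlation), and Nanog stood at -2.04 ± 0.71 (adjusted p = 0.156). None of 67 genes of oxidative phosphorylation (median -0.27) and none of 30 oocyte-expressed genes (median 0.33) passed, with camera adjusted p of 0.000217 and 0.0403, and adjusted p = 0.548 and 0.557 with an estimated correlation. Of 13 trophectoderm genes 2 fell over the list alone (median -0.12, camera adjusted p = 0.135), including Cldn4, a tight junction gene (-3.69 ± 1.03, adjusted p = 0.0958). The medians of the other lists were -0.07 for ribosome biogenesis, -0.19 for primitive endoderm, -0.03 for polarity and junctions, 0.05 for H3K9 demethylases, 0.29 for Polycomb, 0.13 for DNA methylation, 0.09 for stress, 0.89 for interferon response (4 genes), -0.10 for DNA replication, 0.19 for mitosis and -0.003 for mitochondrially encoded genes, and no camera test among them passed. Of the lists that mark other cells, cumulus and granulosa cell genes had 2 measured members and sperm genes 2, too few for a test.

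The 65 h count of genes between wild-type and mutant mRNA was 3 without experiment A, 1 without B, 0 without C and 33 without D, each of which leaves fewer embryos. Of the 33 genes 22 were among the 56. With no replicate block 2 genes passed, with no filter on low counts 598 and in 1 fit of all 12 groups 185. DESeq2 called 584, of which 55 were among the 56.

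**Figure D2:**
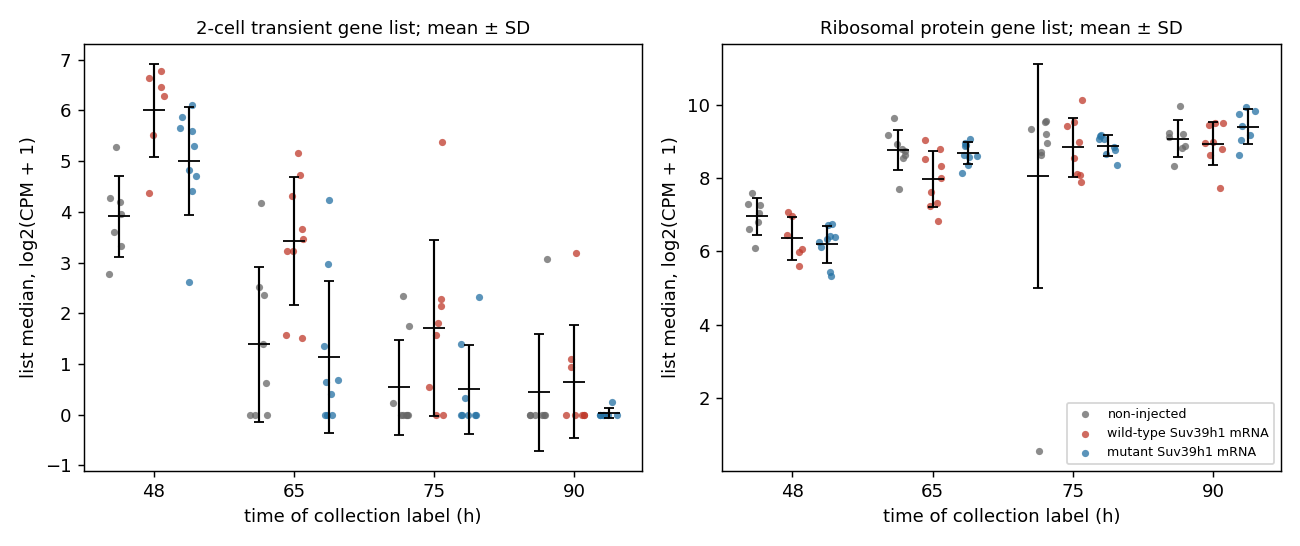
Median level per embryo, as log2(CPM + 1), of the 2-cell gene list (left) and the ribosomal protein gene list (right) by collection time in hours, with 1 point per embryo, colours for the injection groups, and mean ± SD as bars. At 65 h the 2-cell list has a mean of 3.43 after wild-type mRNA, 1.14 after mutant mRNA and 1.39 without injection, and the lowest point on the right is non-injected 75 h replicate 1 at 0.554.

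Against non-injected embryos at 65 h, wild-type mRNA embryos showed 226 genes past the threshold, 127 higher and 99 lower (n = 9 against 8). Usp17lb (4.42 ± 1.00) and Zscan4d (4.76 ± 1.12) rose, as 2 of 18 2-cell genes over all genes and with 3 over the list alone (median 1.60, camera adjusted p = 5.69e-05, adjusted p = 0.335 with an estimated correlation), and both are read with near-identical copies. The p53 target Mdm2 rose by 1.32 ± 0.25 (adjusted p = 0.0118), and the H3K9 factors Suv39h2, the paralog of the injected gene (2.02 ± 0.45, adjusted p = 0.0252), and Atf7ip (1.28 ± 0.35, adjusted p = 0.0498) rose as 2 of 25 on their list. Pluripotency genes fell for 4 of 17 members over all genes and 5 over the list alone (median -0.96, camera adjusted p = 2.79e-05, adjusted p = 0.335 with an estimated correlation), including Tbx3 (-2.66 ± 0.58), Pou5f1 (-1.90 ± 0.49) and Klf4 (-1.48 ± 0.40). Gata6 (-2.95 ± 0.67) and Cldn4 (-4.53 ± 1.18) fell as well. Ribosomal protein genes fell for 41 of 79 members over the list alone and 0 over all genes (median -0.74, camera adjusted p = 1.65e-19, adjusted p = 0.335 with an estimated correlation). Oocyte-expressed genes rose for 6 of 30 over the list alone and 1 over all genes, Omt2a (1.65 ± 0.42; median 1.02, camera adjusted p = 0.000156, adjusted p = 0.335 with an estimated correlation). Genes of oxidative phosphorylation fell for 1 of 67 members and trophectoderm genes for 1 of 13 (medians -0.34 and -0.57, camera adjusted p = 4.70e-06 and 0.0312, adjusted p = 0.394 and 0.335 with an estimated correlation). Rarb, at 2 counts after wild-type mRNA, had 21.2 ± 11.3 CPM without injection (adjusted p = 0.000262). The count was 639 without experiment A, 8 without B, 0 without C and 354 without D. With the Y-linked level as a covariate it was 65, with no filter on low counts 1041, in 1 fit of all 12 groups 395, and DESeq2 called 1155.

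Mutant mRNA embryos at 65 h were not told apart from non-injected embryos gene by gene. In edgeR 0 of 10393 genes passed, with 303 at an unadjusted p below 0.05, while DESeq2 called 198 and edgeR with no filter on low counts 30. The oocyte-expressed list had a median of 0.45 with no member past the test (camera adjusted p = 0.0204, adjusted p = 0.855 with an estimated correlation). That wild-type mRNA gave calls against non-injected embryos and mutant mRNA gave 0 is not itself a test of a difference, which the direct comparison of both mRNAs above provides.

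At 75 h no gene passed in any of the 3 comparisons when edgeR was fitted to the 3 groups of that time. Over 9798 genes, 229 had an unadjusted p below 0.05 for wild-type against mutant mRNA, 893 for wild-type mRNA against no injection and 398 for mutant mRNA against no injection, and DESeq2 called 144, 325 and 221. In the same order edgeR called 17, 282 and 114 genes with no filter on low counts, and 0, 1142 and 705 in 1 fit of all 12 groups. The lowest adjusted p was 0.0992, for wild-type mRNA against no injection. No list passed for wild-type against mutant mRNA with all libraries, and without non-injected 75 h replicate 1 polarity and junction genes did (median -0.42, camera adjusted p = 0.0490, adjusted p = 0.711 with an estimated correlation). Over the list alone 4 of 11 2-cell genes rose after wild-type mRNA and 3 after mutant mRNA, each against non-injected embryos (medians 1.97 and 1.48, camera adjusted p = 0.000108 and 0.00807, adjusted p = 0.328 and 0.504 with an estimated correlation). The mutant call was lost with no replicate block (0.189). The p53 target list had medians of 1.08 and 0.88 with 0 of 19 members past the test in both (camera adjusted p = 0.00595 and 0.000293, adjusted p = 0.354 and 0.408 with an estimated correlation). Stress genes rose for 2 of 15 members after wild-type mRNA over the list alone and for 0 after mutant mRNA, and 0 of 46 ribosome biogenesis genes passed in both. Their medians were 0.58 and 0.15 after wild-type mRNA (camera adjusted p = 0.0191 and 0.0342, adjusted p = 0.5676 and 0.802 with an estimated correlation). After mutant mRNA they were 0.46 and 0.19 (0.00807 and 0.00547, adjusted p = 0.608 and 0.795 with an estimated correlation). After wild-type mRNA 1 of 15 trophectoderm genes rose and 1 fell over the list alone, and 0 of 18 polarity and junction, 0 of 8 primitive endoderm and 0 of 21 Polycomb genes passed. In that order the medians were -0.44, -0.59, -0.50 and -0.43, with camera adjusted p of 0.0191, 0.00595, 0.0191 and 0.0398. With an estimated correlation the adjusted p was 0.524, 0.354, 0.354 and 0.328. The group of non-injected embryos here includes the library that stands apart, and without it the p53 medians were 0.88 and 0.97 and 0 genes passed in each of the 3 comparisons. Several list calls were then lost. After wild-type mRNA stress, ribosome biogenesis and Polycomb genes had medians of 0.43, -0.05 and 0.04 (camera adjusted p = 0.286, 0.464 and 0.653). After mutant mRNA stress and ribosome biogenesis genes had 0.25 and -0.001 (0.156 and 0.597). Other lists gained a call, among them oocyte-expressed genes (0.77 and 0.51, camera adjusted p = 0.0061 and 0.031). With an estimated correlation no list passed. In simulated data of the 75 h design of wild-type against mutant mRNA, 31% of genes changed 4-fold were recovered, over 9798 genes.

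At 90 h wild-type mRNA embryos differed from non-injected embryos in 29 of 10167 genes, 14 higher and 15 lower (n = 8 against 7). Cyclin E1, Ccne1, rose by 1.98 ± 0.34 (adjusted p = 0.0179), and the imprinted genes Cdkn1c, a cell cycle inhibitor (4.12 ± 0.87, adjusted p = 0.0425), and Phlda2 (3.32 ± 0.71, adjusted p = 0.0436) rose, as did Icam1, an adhesion molecule (5.13 ± 1.10, adjusted p = 0.0436). After wild-type mRNA the levels of Cdkn1c, Phlda2 and Icam1 were 35.3 ± 40.4, 51.4 ± 74.6 and 42.2 ± 73.5 CPM, each with an SD above the mean. Without injection they were 1.58 ± 1.16, 6.73 ± 7.98 and 3.30 ± 5.89 CPM. Spp1, osteopontin (-5.68 ± 1.10, adjusted p = 0.0398), P2rx7, an ATP-gated channel (-4.34 ± 0.66, adjusted p = 0.00360), and Epcam, an epithelial adhesion molecule (-1.85 ± 0.38, adjusted p = 0.0404), fell. Dppa1 had 0.131 CPM after wild-type mRNA, from 2 counts over the group, and 57.2 ± 56.6 CPM without injection (adjusted p = 0.00360). Of 16 trophectoderm genes 5 fell and 1 rose over the list alone and 0 passed over all genes (median -0.92, camera adjusted p = 0.000175, adjusted p = 0.428 with an estimated correlation). Of 20 p53 targets 3 rose over the list alone and 0 over all genes, and 18 had a positive fold change (median 0.79, camera adjusted p = 4.20e-05, adjusted p = 0.449 with an estimated correlation). The count was 284 without experiment A, 0 without B, 0 without C and 9 without D. Experiment A held no wild-type mRNA embryo at 90 h. With no replicate block the count was 60 higher and 47 lower. It was 13 with a transcript length offset, 5 without the libraries titled as replicates, 54 with these summed with their namesakes, 677 in DESeq2, 625 with no filter on low counts and 111 in 1 fit of all 12 groups.

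At 90 h only experiments B and D held both wild-type and mutant mRNA embryos, as A held no wild-type and C no mutant mRNA embryo. Wild-type and mutant mRNA embryos at that time showed 0 genes past the threshold in edgeR, with 799 at an unadjusted p below 0.05 and 57 called by DESeq2. With no filter on low counts 63 were higher and 38 lower. Among trophectoderm genes Id2 stood at -3.07 ± 0.81 (adjusted p = 0.473) and Cdx2 at -1.82 ± 0.65 (adjusted p = 0.540), 1 of 16 fell over the list alone, and the median was -0.43 (camera adjusted p = 0.000734, adjusted p = 0.538 with an estimated correlation). None of 79 ribosomal protein genes and none of 67 genes of oxidative phosphorylation passed (medians -0.46 and -0.41, camera adjusted p = 4.27e-13 and 7.59e-07, adjusted p = 0.538 with an estimated correlation for both). None of 20 p53 targets and none of 30 mitosis genes passed (medians 0.23 and 0.25, camera adjusted p = 0.0138 and 0.0229, adjusted p = 0.538 with an estimated correlation for both). The mitosis call was lost with no replicate block (0.303). Mutant mRNA against no injection gave 0 genes in edgeR, with 493 at an unadjusted p below 0.05 and 29 called by DESeq2, 51 with no filter on low counts and 1 in 1 fit of all 12 groups. Its ribosomal protein list had a median of 0.29 with 0 members past the test (camera adjusted p = 2.83e-05, adjusted p = 0.700 with an estimated correlation). None of 20 p53 targets and none of 21 polarity and junction genes passed (medians 0.28 and -0.28, camera adjusted p = 0.00831 and 0.00632, adjusted p = 0.700 with an estimated correlation for both). The p53 call was lost with no replicate block (0.108).

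Because labelled stages differ between groups, embryos of one labelled stage were also compared. Among 9 wild-type and 10 mutant mRNA embryos labelled 4-cell and collected at 65 or 75 h, Map7d2, a microtubule-associated protein gene, was the 1 gene of 9144 to pass in edgeR, at 100.6 ± 45.8 against 292 ± 64.9 CPM (-1.59 ± 0.26, adjusted p = 0.0300), while DESeq2 called 295. It passed under 5 other model settings, but not without any 1 of the experiments (0 genes without A, B or D, and 1 other gene without C). The count was 0 in the 65 h and in the 75 h embryos alone, and 144 with no filter on low counts. Map7d2 lies on the X chromosome, and Xist, the RNA that coats the inactive X of female embryos, was at 7.29 ± 13.1 CPM after wild-type and 108.9 ± 78.9 CPM after mutant mRNA in these embryos (-4.77 ± 1.08, adjusted p = 0.549; named after its values were seen). The Y-linked level was 61.8 ± 45.9 against 37.4 ± 41.8 CPM. The 3 mutant mRNA embryos with the lowest Xist levels (4.92, 6.72 and 13.9 CPM) had Map7d2 at 272, 262 and 331 CPM, and the highest of the 9 wild-type mRNA embryos had 206 CPM. With the Xist level as a covariate Map7d2 did not pass (-1.22, adjusted p = 0.849), and with the Y-linked level it did (-1.64, adjusted p = 0.0167), as 1 of 3 genes. Over the list alone 2 of 13 2-cell genes rose and 0 over all genes (median 1.31, camera adjusted p = 6.43e-05, adjusted p = 0.531 with an estimated correlation). Ribosomal protein and mitochondrially encoded genes had medians of -0.22 and -0.32 with 0 members past the test (camera adjusted p = 3.26e-06 and 0.0114, adjusted p = 0.849 for both with an estimated correlation). Suv39h1 stood at 0.76 ± 0.49 (adjusted p = 0.854). Wild-type mRNA embryos labelled 4-cell against non-injected ones at 65 h (n = 5 against 3) gave 0 genes in edgeR, with 510 at an unadjusted p below 0.05, 30 called by DESeq2 and 31 with no filter on low counts. Over the list alone 1 of 16 pluripotency genes fell and 4 of 19 2-cell genes rose there, and 0 of 79 ribosomal protein genes passed (medians -0.81, 0.49 and -0.39, camera adjusted p = 9.97e-06, 0.0116 and 0.000163). With an estimated correlation the adjusted p was 0.449, 0.575 and 0.950, and the last 2 calls were lost with no replicate block (0.521 and 0.301). Embryos labelled 8-cell (n = 6 against 4), whose collection times differ between the groups, gave 0 genes, with 470, 25 and 32 in the same order. No member passed there on the lists of p53 targets, oxidative phosphorylation, oocyte-expressed, mitochondrially encoded and ribosome biogenesis genes (medians 1.18, 0.42, -0.97, 0.51 and -0.21, camera adjusted p = 1.29e-06, 1.72e-06, 0.000424, 0.00220 and 0.0175). With an estimated correlation the adjusted p was 0.771, 0.848, 0.771, 0.771 and 0.848, and the fourth call was lost with no replicate block (0.190). In simulated data 49% of genes changed 4-fold were recovered in the first of these designs, over 9144 genes, 1% in the second, over 10764 genes, and 8% in the third, over 9493 genes.

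Whether the difference between wild-type and mutant mRNA varied between the collection times was tested over all 12 groups at once. Dppa1 was the 1 gene of 15195 to pass in edgeR (adjusted p = 0.0443), and it is named because it alone passed, chosen after its values were seen, while DESeq2 called 10 genes. Its levels after wild-type and mutant mRNA were 5.07 ± 1.93 and 3.56 ± 1.60 CPM at 48 h (n = 6 and 9), and 0.939 ± 1.52 and 0.183 ± 0.381 CPM at 65 h (n = 9 and 9). They were 0 and 0.850 ± 1.2 CPM at 75 h (n = 8 and 8), and 0.131 ± 0.243 and 5.78 ± 5.70 CPM at 90 h (n = 8 and 7). The count was 0 without any 1 of the experiments and with median-ratio scaling, and 567 with no filter on low counts.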

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

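The tests of explanations here were all chosen after the result was seen, while the measures screened for embryos that stand apart were fixed by rule. The screen covered 36 groups and measures and found 5 embryos far from the nearest other of their group, where about 1.8 would be found by chance.

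Non-injected 75 h replicate 1 had a median correlation of 0.299 with its group, the nearest other embryo having 0.869. Its ribosomal protein list median was 0.554 log2(CPM + 1), below the range of 5.34 to 7.60 over the 22 embryos collected at 48 h, which argues against a swap with one of them. Its total of 2486904 counts is above the median of 1766348 in the other 7 embryos of its group, which argues against a shallow library. Total counts cannot show whether a library failed in another way. Its oocyte list median of 7.004 is far above the other 7 (at most 2.34), and of genes chosen after their values were seen Omt2a had 11290 CPM (at most 35.96 in the other 7), Btg4 4669 CPM (at most 11.6) and Cdx2 0. The label gives this library a stage of 8 to 16 cells (E8-16), which goes against an egg if the label is right. Whether the label belongs to this library was not tested. An egg or an embryo without zygotic transcription stays open and cannot be told apart from other origins, since no group of the design holds either. The bound set for the test, an oocyte median above all 93 other assigned libraries (highest 7.69, at 48 h), was also too strict for embryos that still hold oocyte RNA.

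Wild-type mRNA embryos at 65 h lay earlier than mutant mRNA embryos on the course that non-injected embryos take from 48 h, set to 0, to 65 h, set to 1 (0.604 ± 0.226 against 0.880 ± 0.148, n = 9 and 9, difference -0.276, exact permutation p = 0.00856, adjusted p = 0.0396 over 12 comparisons, two-sided). With libraries thinned to 803780 counts the difference was -0.275 (exact permutation p = 0.00815), which argues against depth as its cause. It was negative in all 4 experiments (-0.254, -0.252, -0.419 and -0.105 for A to D). Both groups held the same number of embryos in each experiment, which argues against a difference between experiments. Among 65 h embryos labelled 4-cell the difference was -0.156 (n = 5 and 7, exact permutation p = 0.107). Among 75 h embryos labelled 4-cell it was -0.026 on the same course (n = 4 and 3, exact permutation p = 0.943). The earlier labelled stage of part of the wild-type mRNA embryos and a slower course at equal stage therefore cannot be told apart, for want of embryos of 1 stage. A candidate explanation is that wild-type Suv39h1 mRNA slows the passage from the 2-cell programme, and this stays a hypothesis found and tested on the same data.

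Injected embryos differed from non-injected embryos at 48 h, when all were labelled 2-cell. Leaving out non-injected 48 h replicates 1 and 3, neither of which the screen flagged, raised the count for mutant mRNA from 116 to 1116, so those libraries are not its source. They are the only 2 non-injected 48 h embryos of experiment B. The rise therefore cannot be told apart from the loss of the comparison within that experiment. Placed on the 48 to 65 h course of the wild-type mRNA group, mutant mRNA embryos lay earlier than non-injected ones (0.103 ± 0.238 against 0.377 ± 0.137, n = 9 and 7, difference -0.275, exact permutation p = 0.0168, adjusted p = 0.0503 over 12 comparisons), and on that of the mutant mRNA group wild-type mRNA embryos did too (difference -0.276, n = 6 and 7, exact permutation p = 0.00991, adjusted p = 0.0396). The difference for mutant mRNA was negative in 4 of 4 experiments and that for wild-type mRNA in 3 of 4 (0.06 in B). Both differences go with a delay of injected embryos of either kind at 48 h, although the first of these fails the correction. They share the same 7 non-injected embryos and are not independent of each other. At 65 h, on the same course, the difference for mutant mRNA was -0.053 (exact permutation p = 0.370). Embryos of 75 and 90 h were placed on the 65 to 90 h course of the same group. That course has other genes and another unit, so its differences are not on the scale of the earlier ones. There the differences for mutant mRNA were -0.018 at 75 h and -0.002 at 90 h (exact permutation p = 0.902 and 0.988). For wild-type mRNA the difference was -0.3 at 65 h, and -0.049 at 75 h and -0.204 at 90 h on the later course (exact permutation p = 0.00522, 0.731 and 0.0420, adjusted p = 0.0396, 0.877 and 0.101). The 75 h values include non-injected 75 h replicate 1, the library that stands apart. Without it the 75 h differences were -0.121 for mutant and -0.148 for wild-type mRNA (exact permutation p = 0.306 and 0.173), negative in 3 and 4 of 4 experiments. A lower position of mutant mRNA embryos at an exact permutation p below 0.05 was thus seen at 48 h only. No group was injected with another RNA, so injection itself and Suv39h1 RNA of either form remain open and untested.

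Suv39h1 in wild-type mRNA 65 h replicate 5 was 152 CPM, the nearest other embryo having 78.4 CPM. Mutant mRNA 75 h replicate 4 had 13184 genes with at least 5 counts, the nearest other having 11163. Mutant mRNA 48 h replicate 8 had a median correlation of 0.810 with its group, the nearest other having 0.852. Wild-type mRNA 90 h replicate 2 had a median correlation of 0.755, the nearest other having 0.870. The difference between wild-type and mutant mRNA in Dppa1 varied between the collection times (adjusted p = 0.0443 in edgeR). The embryo in no group, from experiment A at 65 h, had a Suv39h1 level of 65.1 CPM.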

How the results depend on the processing

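The fits without libraries that stand apart, with sex-linked levels as covariates or with libraries summed were chosen after the result was seen, and the other settings were fixed before the data were examined. Counts are in the order wild-type against mutant mRNA, wild-type mRNA against no injection and mutant mRNA against no injection, each at 48, 65, 75 and 90 h, unless said otherwise, and the cause was not tested except where fewer embryos enter. DESeq2 gave 125, 584, 144 and 57, then 546, 1155, 325 and 677, then 778, 198, 221 and 29, with 1023 between 65 and 75 h and 3348 between 75 and 90 h without injection, 295, 30 and 25 at matched stages (4-cell, 4-cell at 65 h, 8-cell), and 10 for the difference between times. No filter on low counts gave 23, 598, 17 and 1.0e+02 (63 higher and 38 lower), then 295, 1041, 282 and 625, then 434, 30, 114 and 51, with 500 between 65 and 75 h, 144, 31 and 32 at matched stages and 567 for the difference between times. No replicate block, which ignores the pairing of embryos by experiment, gave 2 for wild-type against mutant mRNA at 65 h and 2 at 90 h. It gave 1.1e+02 (60 higher and 47 lower) for wild-type mRNA against no injection at 90 h, 0 for mutant mRNA against no injection at 48 h and 2 for the difference between times, and changed 19 of the list calls. A transcript length offset gave 13 for wild-type mRNA against no injection at 90 h, 63 for mutant mRNA against no injection at 48 h and 2 for the difference between times, where median-ratio scaling gave 0. One fit of all 12 groups gave 185 for wild-type against mutant mRNA at 65 h, 1, 395, 1142 and 111 for wild-type mRNA and 1, 705 and 1 for mutant mRNA at 48, 75 and 90 h against no injection, and 883 and 3441 for the last 2 steps without injection. Without libraries titled as replicates wild-type mRNA against no injection at 90 h gave 5, and 4-cell embryos of 65 h or of 75 h alone gave 0. Without non-injected 48 h replicates 1 and 3 the counts against no injection were 447 and 1116, and without non-injected 75 h replicate 1 the 3 steps without injection gave 5010, 863 and 2958. The Y-linked level as a covariate gave 113 and 363 genes against no injection at 48 h for wild-type and mutant mRNA, 65 for wild-type mRNA at 65 h and 3 for 4-cell embryos, where the Xist level gave 0. Summing the libraries titled as replicates with their namesakes gave 54 and 1 for wild-type and mutant mRNA against no injection at 90 h. With an estimated correlation and all libraries 0 list calls remained of 80.

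Leaving out 1 experiment at a time gave 0 to 33 genes for wild-type against mutant mRNA at 65 h, 0 to 705, 0 to 639 and 0 to 284 for wild-type mRNA against no injection at 48, 65 and 90 h, 0 to 627 for mutant mRNA at 48 h, 78 to 4596, 0 to 540 and 9 to 2737 for the 3 steps without injection, 0 to 1 and 0 to 4 for 4-cell embryos, and 0 to 0 for the difference between times. Over DESeq2, median-ratio scaling, no filter, no replicate block and the length offset, 551 of the values of single named genes stayed on their side of the threshold, 63 lost the call (37 of these with no replicate block), 18 gained it and 3 changed sign, all of them Suv39h1 for wild-type mRNA against no injection at 90 h (0.02), which was -0.056 with no filter, -0.16 with no replicate block and -0.022 with the length offset. The limits for shallow libraries removed 0 libraries, so that setting tests nothing and is not counted here, nor are the fits without an experiment, of all 12 groups or chosen after the result was seen.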

Other observations

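The test of the Suv39h1 transcripts and 15 of the 19 counts over other splits were chosen after the result was seen, and the 4 counts for matched stages and for the difference between times before it. Reads of Suv39h1 in injected embryos at 48 h went more to 1 annotated transcript, Suv39h1-202. Its share of the gene's counts was 0.737 ± 0.142 in 15 injected and 0.559 ± 0.116 in 7 non-injected embryos, a difference of 0.177 (two-sided permutation p = 0.00999), and 0.339, 0.152, 0.050 and 0.336 within experiments A to D. A candidate explanation is that injected mRNA adds reads to the coding part that transcripts share, which kallisto then assigns to 1 of them. The test could have come out the other way, but the injected sequence was not given in the sources used here, so this stays a hypothesis.

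Other splits of the same embryos into groups of the same sizes were refitted, 21 per comparison with the real one, and 56 for 4-cell embryos at 65 h. Only the real split, 1 of 21, reached its count for wild-type against mutant mRNA at 65 h (56 genes, highest other 0), wild-type mRNA against no injection at 48 h (14, highest other 2), 65 h (226, highest other 31) and 90 h (29, highest other 1), mutant mRNA against no injection at 48 h (116, highest other 16), and the 3 steps without injection (3537, 223 and 1814, highest other 0 each). This is the lowest share that 21 splits can give. The splits also did not keep the numbers of each group per experiment, so chance is not excluded for these counts. For the comparisons with 0 genes every split is as large by construction (21 of 21, and 56 of 56 for 4-cell embryos at 65 h), so the splits say nothing about chance there. These are wild-type against mutant mRNA at 48, 75 and 90 h (highest other 41, 0 and 1), wild-type mRNA against no injection at 75 h (highest other 0), mutant mRNA against no injection at 65, 75 and 90 h (highest other 0 each), 8-cell embryos (highest other 10) and 4-cell embryos at 65 h (highest other 13). Other splits reached the real count for wild-type against mutant mRNA in 4-cell embryos (1 gene, 2 of 21 splits, highest other 1) and for the difference between times (1 gene, 5 of 21, highest other 50). For the difference between times the split with 50 genes calls several times the real count, which points to a structure of the embryos that was not tested.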
